A study of Homo sapiens with 6 samples.

How the data were processed

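Poly(A) RNA was sequenced from Ishikawa cells, a human endometrial cancer cell line, in 6 libraries: 3 from cells incubated for 4 days with an extract of the scaffold named PGC, which the labels call the control, and 3 from cells incubated with an extract of the scaffold named PGCL. The labels call the 3 libraries of each group biological replicates. The columns of the PGCL group carry the letters LNG, a common abbreviation of the progestin levonorgestrel, but the labels do not spell it out, and the composition of the extracts is not given in the sources used here. Each column was matched to its sample by the column name that the sample's description states.

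The authors deposited 1 table of whole-number read counts per gene, not normalized. Per the submitters' processing notes, fastp 0.22.0, HISAT2 2.2.0 and featureCounts 2.0.6 were used with the build hg38. The gene annotation, the strand setting of the counting, the treatment of reads that fit several places and any filter on genes are not given in the sources used here. The table held 17002 genes, each with a total of at least 6 counts and with counts in at least 3 libraries. Because the strand setting is unknown, reads of genes with overlapping exons cannot be told apart. The exons of 46.9% of the tested genes, and of 48 of the 112 tested genes selected by the rule given below, overlapped those of another annotated gene. Identifiers were matched to GENCODE release 29 (GRCh38), which held 16892 of the 17002. Coordinates, biotypes, exon overlaps, GC content and transcript lengths were taken from it, and coordinates are 1-based. The share of each gene's 50-base words found in other annotated genes was computed from the longest transcript, with a word every 10 bases.

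Total counts per library were 18964887, 17648101 and 19452865 in the PGC group and 18653794, 17475465 and 14794835 in the PGCL group. A count of 0 allowed up to 3 counts, which was 0.154 to 0.203 CPM (counts scaled to the library total) depending on the library, for counting error only. Mitochondrially encoded genes took 5.99% to 6.15% of the counts. Every pair of libraries differed by more than sampling noise. The share of genes past a chi-square test at 5% was 17.4% to 23.7% within groups and 44.0% to 47.7% across groups. It was taken over the 9936 to 10328 genes per pair with the higher counts. This argues against columns that repeat 1 library, but cannot show that the cultures were independent. Each library was counted as 1 replicate because the labels call them biological replicates.

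Genes were kept by edgeR's filterByExpr (minimum count 10, minimum total 15), which left 13667 genes and removed 3335. Counts were scaled by TMM, and the groups were compared with edgeR 4.0.16 (R 4.3.3) by glmQLFit and glmQLFTest with group as the only term. The p-values, two-sided, were adjusted by Benjamini-Hochberg, with a threshold of 0.05. The common biological coefficient of variation was 0.0612. Values given as CPM are TMM-scaled, and errors are SD over 3 libraries for CPM and SE for log2 fold changes, which are PGCL over PGC.

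The test, the 38 gene lists and the rule for named genes were fixed before the data were examined. Lists with at least 5 tested genes (33 of the 38) were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the lists. Camera with an estimated correlation and fry were alternatives. The rule named the 10 protein-coding genes per direction with the largest fold change among those past the threshold, with a mean of at least 50 counts and no overlap between the groups. It also named 10 genes chosen for the tissue and treatment (among them PGR, ESR1, FKBP5, ZBTB16, HSD17B2, PAEP, MKI67, CCND1 and CDKN1A), and up to 3 members per list with the smallest p past the threshold. List members named beyond these were chosen after their values were seen. Some genes that the rule or the lists name are not reported here.

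The alternatives were RLE and upper-quartile scaling, no filter, a filter of at least 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, the replicate number as a block, leaving out each library in turn, and a fold threshold of 2. A robust fit, removal of the trend with GC content and transcript length, and leaving out genes whose replicates lay far apart were added after seeing the data. Such genes had a range over 1.5 on the log2 scale within a group and a highest count above 150. There were 76 of them.

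The tests were tested on simulated data with the real libraries' means and sizes and 200 changed genes in each of 4 draws over 13667 genes for the comparison of PGCL with PGC. With gene-wise dispersions, 41.0% of genes changed 1.25-fold, 63.0% of those changed 1.5-fold, 81.5% of those changed 2-fold and 93.0% of those changed 4-fold were called in the right direction, and 8.84% of all calls were false. With trended dispersions 4.27% were false. A simulated shift of −0.2 in the glycolysis list was called with a mean of −0.22, and 0 of the other lists were called. Each gene was drawn independently of the others, so this simulation cannot show how list calls hold where genes are correlated. The 200 changed genes per draw were also far fewer than the 3562 called in the data. The recovered and false shares depend on that number, so they do not carry over to the real calls. XIST and Y-linked genes were left out of the named genes.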

Results

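The dataset consisted of gene counts from Ishikawa cells, an established human endometrial cancer line, after 4 days with an extract of a PGC scaffold (control) or of a PGCL scaffold. There were 3 libraries per group, with totals of 14794835 to 19452865 counts. The series title places the PGCL scaffold, made of short fibers, in the setting of endometrial hyperplasia, an overgrowth of the uterine lining. The comparison therefore addressed which transcripts differed between endometrial epithelial cancer cells given the PGCL extract and those given the PGC extract. Nothing in the labels says how the replicate cultures were kept apart beyond naming them biological replicates. Adjusted p-values of genes are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and those of gene lists from camera.

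With the PGCL extract, metallothionein transcripts rose most among the genes selected for fold change, NRF2 target genes rose as a group, and targets of the hypoxia-inducible factors (HIF), glycolytic genes and G2/M genes fell. With an estimated correlation between genes, the NRF2, HIF, glycolysis and G2/M lists did not pass (adjusted p = 0.058, 0.10, 0.31 and 0.080). In all, 1768 genes were higher and 1794 were lower among 13667 tested. Most changes were small, with a median absolute log2 fold change of 0.26 among the 3562 called genes. A change of at least 2-fold was found for 62 of the higher and 200 of the lower genes. The groups did not overlap for 5538 genes (40.5%), where chance gives 10%. The first principal component, with 43.7% of the variance, separated the groups.

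**Figure D1:**
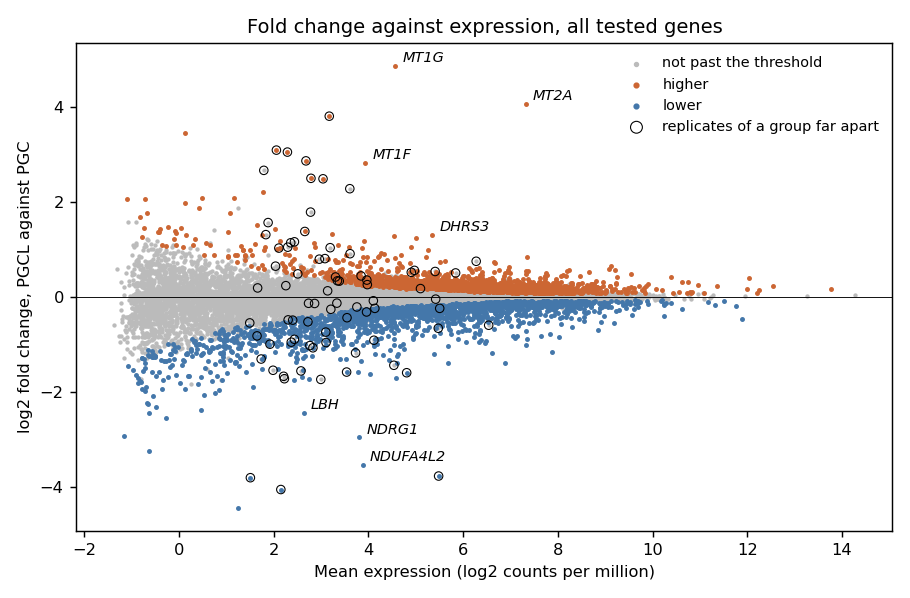
Log2 fold change (PGCL over PGC) against mean expression (log2 CPM) for the 13667 tested genes, with called genes in color and black rings around the 76 genes with a count above 150 whose replicates range over more than 1.5 (log2) within a group. MT1G (4.88) and MT2A (4.08) lie at the top, and NDUFA4L2 (−3.54) and NDRG1 (−2.96) near the bottom.

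Metallothioneins, small cysteine-rich proteins that bind zinc and copper, showed the steepest rise among the genes selected for fold change. MT1G (ENSG00000125144, chromosome 16, 56666731 to 56668065, minus strand) rose from 1.54 ± 0.030 to 45.7 ± 1.34 CPM (SD, n = 3 per group), 29.4-fold, with a log2 fold change of 4.88 (SE 0.09, adjusted p = 1.5e-12). MT2A (chromosome 16, 56608199 to 56609497) rose 16.9-fold, from 17.9 ± 3.0 to 301 ± 22.1 CPM (adjusted p = 2.3e-12). MT1F (chromosome 16, 56657694 to 56660698) rose 7.07-fold, from 3.78 ± 0.14 to 26.8 ± 1.30 CPM (adjusted p = 1.0e-09). SLC30A1, which exports zinc from the cell, rose with a log2 fold change of 0.55 (SE 0.03, adjusted p = 9.8e-08). These were the 4 tested members of the list, too few for a list test, and all 4 also passed when adjusted over the list alone. Of the members below the filter, MT1X had 1, 4 and 3 counts in the PGC libraries and 9, 32 and 18 in the PGCL libraries. MT1H had 0 counts in each PGC library and 2, 2 and 3 in the PGCL libraries. Metallothionein genes resemble one another, and 13.8% of the 50-base words of MT1G occur in other annotated genes, so the split between members is uncertain.

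Of the 16 tested targets of NRF2, the transcription factor that raises antioxidant and detoxifying enzymes, 15 rose and 0 fell, also when adjusted over the list alone. Their mean log2 fold change was 0.54 (adjusted p = 1.6e-10). With an estimated correlation the adjusted p was 0.058. NQO1, a quinone reductase, rose from 476 ± 7.98 to 707 ± 18.1 CPM (SD, n = 3), with an adjusted p of 9.7e-09 in edgeR's test. TXNRD1, thioredoxin reductase, rose from 618 ± 4.10 to 867 ± 15.8 CPM. OSGIN1 rose 2.43-fold, from 13.5 ± 0.10 to 32.8 ± 1.16 CPM. HMOX1, heme oxygenase, was the member that did not pass (log2 fold change −0.31, SE 0.24, adjusted p = 0.39).

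Targets of HIF, which is stabilized when oxygen is low, went the other way: 14 of 18 fell and 2 rose, with 15 and 2 when adjusted over the list alone. Their mean log2 fold change was −0.64 (adjusted p = 5.5e-08), and the adjusted p was 0.10 with an estimated correlation. NDRG1 (chromosome 8, 133237171 to 133302022) fell from 24.8 ± 1.02 to 3.16 ± 0.70 CPM, 7.78-fold (adjusted p = 5.4e-09). BNIP3, a mitophagy receptor, fell from 118 ± 0.53 to 61.3 ± 1.2 CPM. The members that rose were SLC2A1, the glucose transporter (log2 fold change 0.22), and ANGPTL4 (0.48). Of 19 glycolysis genes, 14 fell and 2 rose, also when adjusted over the list alone. The mean log2 fold change was −0.33 (adjusted p = 3.8e-05), and the adjusted p was 0.31 with an estimated correlation. PFKFB3 and PFKFB4, which set the level of the glycolytic activator fructose 2,6-bisphosphate, had log2 fold changes of −0.78 (SE 0.03) and −1.21 (SE 0.07). PGK1 had −0.55 (SE 0.03). LDHA, among those that fell, was at 13.2 CPM with PGC and 8.80 with PGCL extract, and ALDOA at 1.09 and 1.12. GAPDH was at 3007 and 2821 CPM. Low values also occurred in other lists. RPS3A was at 1.52 CPM with PGC and 1.28 with PGCL extract, beside RPL3 at 2422 and 2415. FTH1, of the NRF2 list, was at 9.50 and 19.6, beside FTL at 1155 and 1537. The reason for these low values was not tested, and whether all reads of such genes were counted is not known. The calls of LDHA and FTH1 are therefore uncertain. PFKFB4, ENO2 and SLC2A1 belong to both lists.

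**Figure D2:**
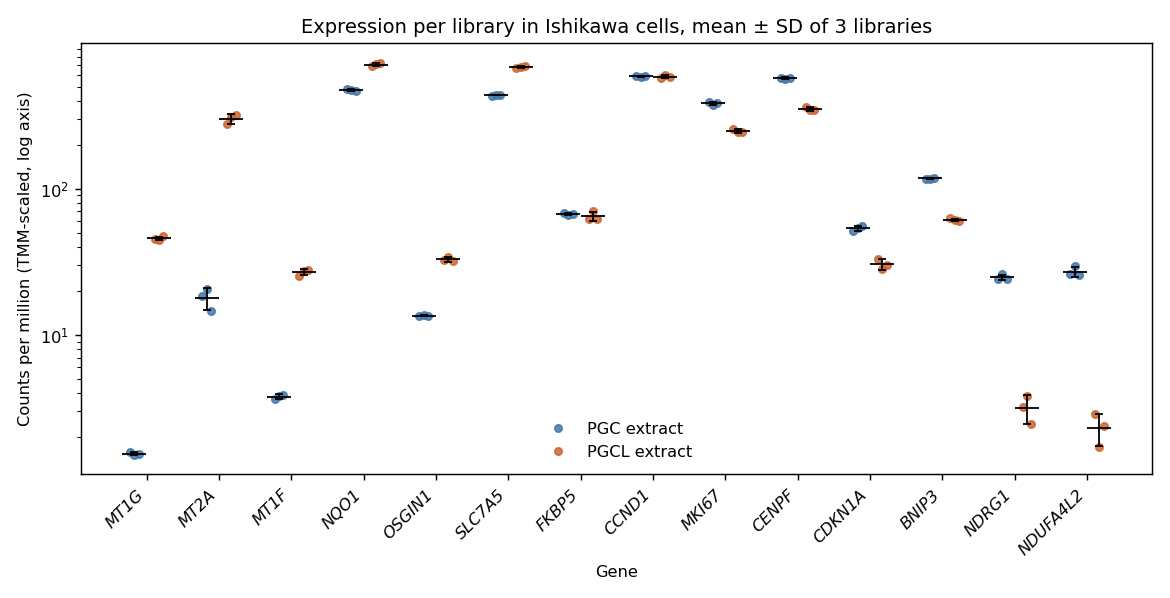
Expression of 14 genes in each library (points, TMM-scaled CPM on a log axis) with the mean and SD of 3 libraries per group (black). MT1G lies at 1.54 CPM with PGC extract and 45.7 with PGCL extract, NDRG1 at 24.8 and 3.16, and the points of FKBP5 and CCND1 overlap between the groups.

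Among the other lower genes selected for fold change, NDUFA4L2 (chromosome 12, 57234903 to 57240715) fell 11.6-fold, from 27.1 ± 2.11 to 2.32 ± 0.58 CPM (adjusted p = 2.4e-09). Its exons overlap another annotated gene. LBH fell 5.43-fold, from 10.5 ± 0.52 to 1.93 ± 0.16 CPM (adjusted p = 1.4e-07). DTX4, PPFIA4, LINGO1, NEURL1B, NTSR1, which encodes a neurotensin receptor, and NXPH4 fell with log2 fold changes of −1.89 to −1.61. Among the other higher genes, DHRS3, a retinaldehyde reductase, rose from 23.4 ± 0.75 to 58.1 ± 1.80 CPM (adjusted p = 8.6e-09). MAGEB4 and ZNF114 rose with log2 fold changes of 1.52 and 1.42. SMPD4, TIMM22, PYCR3 and AAAS, also selected, were uncertain. SMPD4 (log2 fold change 2.49) and TIMM22 (1.38) rested on PGCL replicate 3, without which they had 0.57 (adjusted p = 0.092) and 0.28 (adjusted p = 0.35). Leaving out PGC replicate 1, 2 or 3 also ended both calls, with adjusted p-values of 0.052, 0.069 and 0.061 for SMPD4 and 0.083, 0.12 and 0.11 for TIMM22. PYCR3 (−3.81) had 85, 30 and 191 counts in the PGC libraries and 7, 8 and 4 in the PGCL libraries, and its value was −3.02 without PGC replicate 3. AAAS (2.21) had 29, 117 and 128 counts in the PGCL libraries, against 27, 19 and 22, and was not called by limma-voom (adjusted p = 0.055) or a robust fit (adjusted p = 0.11). The robust fit, chosen after seeing the data, also ended the call of PYCR3 (adjusted p = 0.0501), and both it and limma-voom ended those of SMPD4 and TIMM22.

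Genes of G2/M and mitosis fell: 20 of 28 were lower and 3 were higher, with 21 and 3 when adjusted over the list alone. Their mean log2 fold change was −0.27 (adjusted p = 3.2e-08), and the adjusted p was 0.080 with an estimated correlation. CENPF, a kinetochore protein, fell from 572 ± 5.30 to 351 ± 11.3 CPM (adjusted p = 2.3e-09). MKI67, the gene of the proliferation marker Ki-67, fell from 384 ± 9.66 to 248 ± 6.10 CPM (adjusted p = 9.3e-09). TPX2, a spindle assembly factor, had a log2 fold change of −0.45 (SE 0.03). BIRC5, FOXM1 and HMMR were the members that rose. Of 30 genes of G1/S and replication, 8 rose and 8 fell (8 and 12 when adjusted over the list alone), and the list was not called (adjusted p = 0.71). CHAF1A rose (log2 fold change 0.33), and UNG (−0.27) and UHRF1 (−0.32) fell. CCND1, cyclin D1, was at 586 ± 5.38 and 584 ± 11.4 CPM (log2 fold change −0.0055, SE 0.02, adjusted p = 0.90).

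Inhibitors of cyclin-dependent kinases and related antiproliferative genes also fell, with 6 of 14 lower and 0 higher (7 and 0 when adjusted over the list alone). The mean log2 fold change was −0.39 (adjusted p = 0.0014), with an adjusted p of 0.10 under an estimated correlation. CDKN1A, encoding p21, fell from 53.6 ± 1.90 to 30.5 ± 2.58 CPM (adjusted p = 2.1e-06). CCNG2 and CDKN2D had log2 fold changes of −0.47 and −0.72. The p53 target list, which shares CDKN1A, was not called (6 rose and 2 fell of 24, 6 and 3 when adjusted over the list alone, adjusted p = 0.77). CCNG1 rose (0.26) and PHLDA3 fell (−0.97). The pro-apoptotic list was not called either (5 rose and 2 fell of 23, also when adjusted over the list alone, adjusted p = 0.95). Its member PMAIP1, encoding NOXA, rose 2.49-fold, from 5.35 ± 0.71 to 13.3 ± 1.01 CPM (adjusted p = 9.4e-06). CYCS rose (0.28), and APAF1 fell (−0.37). Of 9 anti-apoptotic genes 3 rose and 0 fell, also when adjusted over the list alone (list adjusted p = 0.39). They were BCL2L1 (0.31), BCL2L2 (0.25) and BAG1 (0.18). The call of BAG1 was lost without any of PGC replicates 2 and 3 and PGCL replicates 2 and 3 (adjusted p of 0.064 to 0.092).

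The list of progestin-raised genes, which was not limited to genes of the epithelium, was not called (adjusted p = 0.77). Of 14 tested, 3 rose and 2 fell, also when adjusted over the list alone, and the mean log2 fold change was −0.05. SPP1, osteopontin, rose from 25.6 ± 0.39 to 50.5 ± 0.96 CPM (adjusted p = 8.1e-08). TSC22D3 rose slightly (log2 fold change 0.16, SE 0.04), and MAOA fell (−0.47, SE 0.06). FKBP5, a target of progesterone and glucocorticoid receptors, was at 67.0 ± 1.34 and 64.6 ± 4.66 CPM (log2 fold change −0.05, SE 0.05, adjusted p = 0.54). The list of secretory-phase and receptivity genes, which shares SPP1 and MAOA, was not called (2 rose and 1 fell of 13, also when adjusted over the list alone, adjusted p = 0.76). CD55 rose (0.27). Of 14 steroid receptors and coregulators 1 rose and 5 fell, also when adjusted over the list alone (list adjusted p = 0.71). SOX17 rose (0.31), PAQR8, a membrane progestin receptor, fell (−1.06), and NR3C1, the glucocorticoid receptor, fell (−0.19), a call lost without PGCL replicate 3 (adjusted p = 0.051). ESR1 had 3, 2 and 4 counts in the PGC libraries and 0, 1 and 0 in the PGCL libraries, too few to be tested. PGR, ZBTB16, HSD17B2 and PAEP were not analysed here.

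The estrogen-induced list was not called (5 rose and 3 fell of 20, 5 and 5 when adjusted over the list alone, adjusted p = 0.77). KRT19 fell (log2 fold change −0.55), and CTSD (0.40) and RBBP8 (0.29) rose. CTSD shares 60.6% of its 50-base words with other annotated genes, and DDIT4, SMPD4, BCL2L1, KRT18, UHRF1, PHLDA3, MT-ND2 and MT-ND1 share 20% to 44.1%, so their counts are uncertain. The exons of NQO1, OSGIN1, SLC7A5, CDKN1A, PGK1, PFKFB4, IDI1, LOXL2, MAGEB4 and ZNF114 overlap those of another annotated gene. Of 8 androgen-induced genes 1 rose and 4 fell, also when adjusted over the list alone (list adjusted p = 0.17). NDRG1 and SLC45A3 (−0.66) fell, and ACSL3 rose (0.32). Of 12 genes of steroid and prostaglandin metabolism 4 rose and 1 fell, with 4 and 2 when adjusted over the list alone (list adjusted p = 0.71). Steroid sulfatase, STS, rose from 19.1 ± 0.79 to 31.2 ± 1.5 CPM (adjusted p = 7.3e-06), AKR1C3 rose (0.54) and PTGS1 fell (−0.81). The mean of this list was 0.09 and its median −0.05.

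Genes of the ATF4 and amino acid response rose, with 11 of 21 higher and 2 lower, and 13 and 2 when adjusted over the list alone. The mean log2 fold change was 0.35 (adjusted p = 0.00027), and the adjusted p was 0.10 with an estimated correlation. SLC7A5, a leucine transporter, rose from 436 ± 1.97 to 682 ± 11.8 CPM (adjusted p = 1.7e-09). PSAT1, a serine synthesis enzyme, rose from 332 ± 5.29 to 478 ± 9.89 CPM. The members that fell were DDIT4, an inhibitor of mTORC1 that is also a HIF target (−0.95), and ATF3 (−0.81). The list of chaperones and other genes of endoplasmic reticulum stress was not called (3 rose and 5 fell of 18, also when adjusted over the list alone, adjusted p = 0.95). HERPUD1 rose (0.40), and HSP90B1 (−0.24) and HSPA5 (−0.12) fell.

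Cholesterol synthesis genes rose, with 14 of 24 higher and 2 lower, and 15 and 2 when adjusted over the list alone. The mean log2 fold change was 0.19 (adjusted p = 9.7e-06), and the adjusted p was 0.10 with an estimated correlation. IDI1, isopentenyl diphosphate isomerase, rose from 97.2 ± 2.55 to 137 ± 8.03 CPM (adjusted p = 2.4e-06). INSIG1 rose (0.29), while TM7SF2, a sterol reductase, fell (−0.62). Of 12 fatty acid synthesis genes 7 rose and 1 fell, also when adjusted over the list alone (list adjusted p = 0.0083, and 0.23 as the adjusted p with an estimated correlation). ME1 (0.44), ACSL3 (0.32) and SREBF1 (0.29) rose. The median was 0.10, the mean 0.015, and the mean on the log2 CPM scale that camera tested −0.00078, which ran from −0.047 to 0.16 over the alternatives, so its sign is uncertain. ACACA had −1.60, with counts of 617, 514 and 1278 in the PGC libraries and 482, 146 and 98 in the PGCL libraries. ME1 is also an NRF2 target.

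Genes of the extracellular matrix and its remodelling fell, with 14 of 20 lower and 3 higher (14 and 4 when adjusted over the list alone). The mean log2 fold change was −0.33 (adjusted p = 0.00039), and the adjusted p was 0.35 with an estimated correlation. COL6A2 fell from 177 ± 9.57 to 97.0 ± 4.13 CPM (adjusted p = 1.7e-08). LOXL2, which crosslinks collagen, fell 2.97-fold, from 20.5 ± 1.66 to 6.86 ± 1.04 CPM, and COL6A1 had −0.43. Of 10 genes of epithelial-mesenchymal transition 2 rose and 3 fell, also when adjusted over the list alone (list adjusted p = 0.71). ITGA5 (−1.27) and FN1 (−0.52) fell, and TAGLN rose (1.03). Of 18 epithelial genes 4 rose and 6 fell, also when adjusted over the list alone (list adjusted p = 0.81). The keratin genes KRT19 and KRT18 (−0.19) and the E-cadherin gene CDH1 (−0.23) were among those that fell. Mean and median differed in sign for the estrogen-induced (−0.11 and 0.0042), pro-apoptotic (−0.00057 and 0.0084) and epithelial (−0.011 and 0.053) lists, none of which was called.

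**Figure D3:**
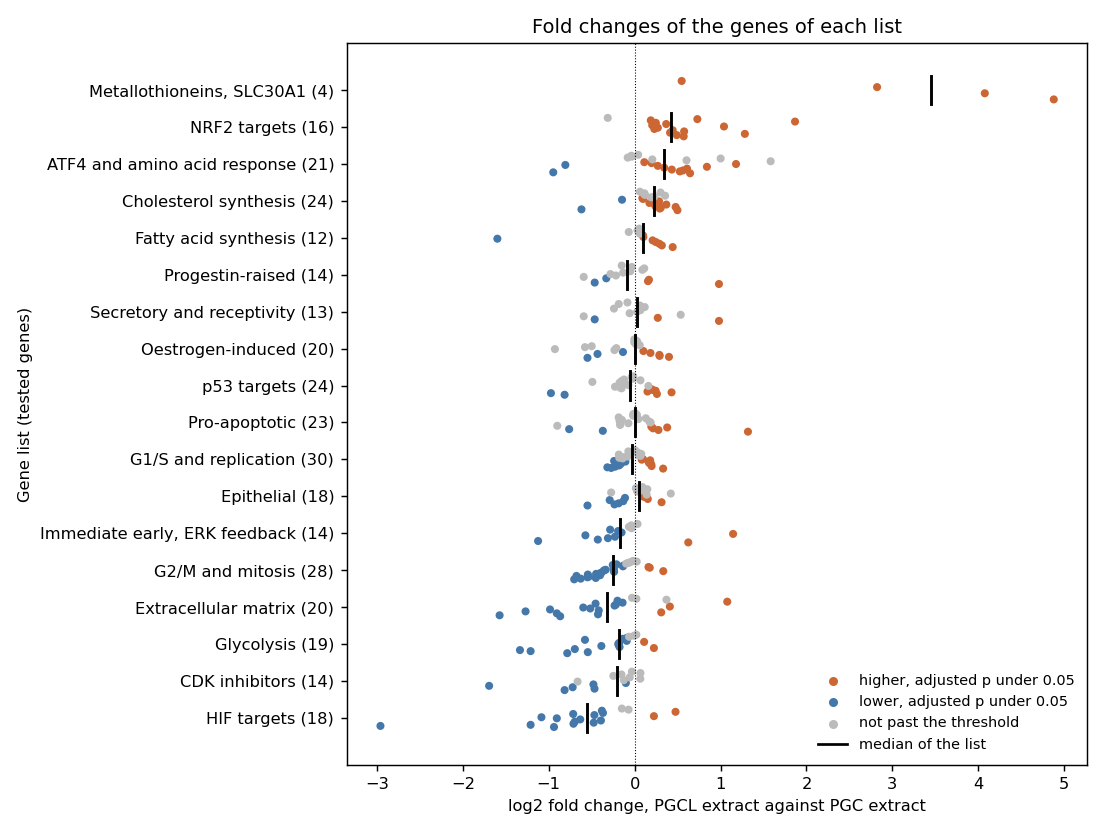
Log2 fold changes (PGCL over PGC) of the tested genes of 18 lists, 1 point per gene, with the number of tested genes in parentheses and the median as a black bar. Points of the NRF2 list (median 0.43) lie to the right of 0 except for HMOX1, and most points of the HIF list (median −0.56) lie to the left.

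Markers of other cell types gave few tested genes and no common direction. Of 3 ciliated cell genes, FOXJ1 (22 ± 1.1 to 13.4 ± 0.66 CPM) and RSPH1 (0.98 ± 0.14 to 0.25 ± 0.044 CPM) fell. Of 3 stromal genes COL1A2 rose (440 ± 20.7 to 546 ± 21.6 CPM), THY1 rose (0.53 ± 0.18 to 1.38 ± 0.22 CPM) and COL1A1 fell (8.40 ± 0.50 to 4.23 ± 0.23 CPM), beside the fall of the matrix list, which also holds both collagens. The call of THY1 was lost without PGC replicate 2 (adjusted p = 0.056). Of 3 endothelial genes VWF rose (3.41 ± 0.76 to 5.60 ± 0.73 CPM), a call lost without PGC replicate 2 (adjusted p = 0.063) or PGCL replicate 1 (adjusted p = 0.067). The counts of these 3 lists were the same when adjusted over each list alone. Of the lists for RNA quality, mitochondrially encoded genes (4 rose and 2 fell of 13, 5 and 2 when adjusted over the list alone), replication histones (0 and 0 of 6, also over the list alone) and ribosomal proteins (5 and 3 of 72, 2 and 0 over the list alone) were not called, with adjusted p-values of 0.20, 0.38 and 0.71. MT-ND2 (0.39) and MT-ND1 (0.17) rose, and MT-ND5 fell (−0.20). RPS23 (0.35), RPL22 (0.15) and RPL13A (0.08) rose. The call of RPL13A was lost without PGC replicate 2, PGC replicate 3 or PGCL replicate 1 (adjusted p of 0.0504 to 0.058) and under upper-quartile scaling (adjusted p = 0.060). The mean of the ribosomal list was −0.04, while its median (0.0072) and the direction of its test were above 0. RPL7A, one of the 3 that fell (log2 fold change −3.78), shares 49.1% of its 50-base words with other annotated genes and had 4211 counts in PGC replicate 2 against 118 and 143 in the other PGC libraries and 76 to 133 in the PGCL libraries. Without it the mean was 0.014.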

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

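The robust fit, the removal of the GC and length trend and the runs without erratic genes (a range over 1.5 on the log2 scale within a group) were chosen after seeing the data. No called gene was called in the other direction in any alternative. A change of direction without a call was not counted over all genes. The count of higher genes ran from 1416 (upper-quartile scaling) to 1963 (GC and length offset) with all libraries, and from 1250 to 1618 when 1 library was left out. The count of lower genes ran from 1467 (DESeq2) to 2055 (upper-quartile scaling), and from 1389 to 1570 with 1 library left out, in fits with fewer samples. A fold threshold of 2 left 62 higher and 200 lower genes by its construction. Of the 112 named genes, 100 kept their direction and their side of the threshold in every alternative run on them. Replicate numbers did not pair the libraries: same-numbered libraries had correlations of 0.044, 0.016 and −0.040 across genes, and PGC replicates 2 and 3 did not correlate best with their own number. The replicate block gave 1537 higher and 1563 lower genes, kept 85.2% and 86.2% of the calls, and ended those of TIMM22 (adjusted p = 0.055) and of the immediate early list (adjusted p = 0.051). With an estimated correlation 0 lists were called higher and 0 lower, against 4 and 6 with the preset one, and 7 lists had an unadjusted p under 0.05 with the estimated one. Fry, which does not compare a list with other genes, called 11 higher and 11 lower. The direction of a list is that of its test, which can differ from the sign of its mean. The following changes of direction had no call in camera, and the cause was not tested. For the progestin list fry gave the direction up (mean −0.050, adjusted p = 0.040, range over the alternatives 0.040 to 0.90), and for the pro-apoptotic list the direction down (mean −0.00046). With 1 library left out, direction changed for the pro-apoptotic list (means of −0.025 to 0.029), endoplasmic reticulum stress (0.0037 to 0.052), the epithelial list (−0.052 to 0.030), ribosomal proteins (−0.060 to 0.0075) and CCND1 (−0.024 to 0.0074). Without the GC and length trend, the tests of endoplasmic reticulum stress and ribosomal proteins changed direction while the means (0.027 and −0.032) kept their signs. Without erratic genes endoplasmic reticulum stress changed direction (mean −0.0065). The mean took both signs over the alternatives for 10 of 33 lists. Of these only fatty acid synthesis was called (−0.047 to 0.16), and its test kept the direction up. The lists not yet mentioned were receptivity (−0.015 to 0.066), heat shock (−0.0050 to 0.078), epithelial-mesenchymal transition (−0.095 to 0.0014), NF-kB targets (−0.11 to 0.0038) and replication histones (−0.0034 to 0.21). In the simulation, with only 200 changed genes per draw, 63.0% of genes changed 1.5-fold were recovered over all expression levels. ESR1, MT1X and MT1H had too few counts to be tested.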

Other observations

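Genes outside the lists described so far also moved. Of 14 immediate early genes and feedback regulators of ERK signaling 8 fell and 2 rose, also when adjusted over the list alone (mean log2 fold change −0.12, camera adjusted p = 0.026). The call was lost without PGCL replicate 3 (adjusted p = 0.076), with the replicate block (adjusted p = 0.051) and with an estimated correlation (adjusted p = 0.49). FOS fell from 30.3 ± 2.37 to 13.9 ± 0.98 CPM (SD, n = 3, edgeR adjusted p = 6.1e-07) and DUSP6, which shares 36.5% of its 50-base words with other annotated genes, had −0.43, while DUSP4 (0.62) and EGR1 (1.15) rose. Of 14 Wnt targets 1 rose and 4 fell (1 and 6 when adjusted over the list alone), and the list was not called (adjusted p = 0.15). LGR5 (−0.49), TNFRSF19 (−1.32) and NOTUM (−0.97) fell. Of 10 targets of TGF-beta and YAP 3 rose and 3 fell (4 and 4 over the list alone, list adjusted p = 0.77). CCN1 rose from 117 ± 2.71 to 210 ± 6.55 CPM, and TGFBI (−0.16) and LTBP2 (−0.69) fell.

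Of 6 targets of the aryl hydrocarbon receptor 3 rose and 1 fell, also when adjusted over the list alone (list adjusted p = 0.062, and 0.035 without PGC replicate 3). CYP1A1 rose (0.73), NQO1 rose as an NRF2 target too, and ALDH3A1 fell (−0.37), a call lost without PGC replicate 3 (adjusted p = 0.11) or PGCL replicate 2 (adjusted p = 0.079). Interferon response genes (4 rose and 1 fell of 18, adjusted p = 0.25), inflammatory NF-kB targets (0 and 1 of 12, adjusted p = 0.96) and nuclear genes of oxidative phosphorylation (6 and 1 of 30, adjusted p = 0.15) were not called, with the same counts adjusted over each list alone. SDHB, among the 6 oxidative phosphorylation genes that rose (3.81), had 713 counts in PGCL replicate 3. It had 20 in each of the other PGCL libraries and 24, 20 and 22 in the PGC libraries, so its rise is uncertain. IFIT3 (0.24) and USP18 (0.29, lost without PGC replicate 2 with an adjusted p of 0.057, and sharing 23.1% of its 50-base words with other annotated genes) rose, TNFAIP2 fell (−0.51, in a list with a mean of −0.029 and a median of 0.024), and UQCRFS1 (0.24), UQCRC1 (0.16) and COX4I1 (0.16) rose. Of 11 heat shock genes 2 rose and 2 fell (4 and 2 over the list alone, list adjusted p = 0.71). HSPB1 fell (−0.37), and DNAJA1 (0.20) and HSPA8 (0.10) rose.

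The tests of pseudoautosomal genes, of neighbouring genes, of steroid receptor targets, of SLC30A1, of unscaled counts and of TFRC below were chosen only after the result was seen. Splitting the 6 libraries in all 10 ways into 3 and 3, the real split alone (1 of 10) gave as many as 3562 genes, and the highest other count was 1. For called lists it was also 1 of 10, with 10 lists in the real split and at most 6 in the others. The 10 splits are too few for a share under 0.05. The other splits put libraries of both groups on each side, so the group difference widens their spread and lowers their gene counts. Those counts are therefore no measure of what chance gives.

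In 76 of 9901 genes with a count above 150, the libraries of a group ranged over more than 1.5 on the log2 scale. They include 12 called genes, all changed at least 2-fold, and no library stood out, being the farthest in 10 to 15 genes each. Of 7 tested pseudoautosomal genes, which lie on both sex chromosomes in the reference, 4 (57.14%) were such genes, against 0.728% of the others (Fisher's exact test, one-sided, p = 1.1e-07). Another such gene was among the 3 nearest on each side for 48.68% of them, against a mean of 4.46% in 10000 random draws (permutation test, one-sided, p = 0.0001, the smallest they can give). A candidate explanation is therefore reads that fit several copies of a region in the reference used for alignment, assigned differently from library to library; that reference was not used here. Sharing with annotated paralogs or pseudogenes remains open, with a median of 1.423% of 50-base words shared against 0.694% (permutation test, one-sided, p = 0.13), and no biological explanation was tested.

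For the rise of metallothionein and NRF2 target genes, depth was looked at in unscaled sums of the metallothioneins. MT1G, MT2A and MT1F were at least 6.352 times higher in the PGCL group, whose summed depth was the lower. A lower depth cannot raise counts, so depth does not account for the metallothionein rise. The outcome followed from the CPM values and library totals given above, so it adds no separate support. The NRF2 list was not part of that comparison. Activation of a steroid receptor stays open. The test was first made on FKBP5, TSC22D3, PER1, KLF9, SGK1 and ERRFI1, where the highest upper 95% limit of log2 fold change was 0.4142 (SGK1), under 1.5-fold. It was widened to all 14 tested genes of the progestin list after the values were seen, because that choice left out SPP1, which rose (0.98) and has an upper limit of 1.096. The rise of SLC30A1 (log2 fold change 0.5474), which the metal sensor MTF1 raises, decides nothing about metal ions, because SLC30A1 belongs to the list whose rise is to be explained. Metal ions stay open. The difference between the extracts themselves stays open as the biological explanation.

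For the fall of G2/M and HIF target genes, a trend with GC content or transcript length is argued against as the whole cause. With it removed the means were −0.2695 (G2/M, −0.2653 before) and −0.634 (HIF, −0.6357 before), still past the threshold with the preset correlation. With an estimated correlation neither list passed before the removal (adjusted p = 0.080 and 0.10). More iron in the cells, which may lower HIF by activating its hydroxylases, stays open. The transcript of TFRC, which iron-loaded cells degrade, was higher (log2 fold change 0.2501, edgeR adjusted p = 2.2e-06). TFRC is 1 transcript chosen after the result was seen, so it cannot decide the question. The ferritin genes FTL (0.41) and FTH1 (1.04), members of the NRF2 list, also rose. FTH1 was at only 9.50 CPM with PGC and 19.6 with PGCL extract, against 1155 and 1537 for FTL, so its value is uncertain. Culture density and oxygen at harvest were not tested and stay open, as does an effect of the extract.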
